A study of Mus musculus with 10 samples.

How the data were processed

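The series compared mouse keratinocytes lacking RhoA, a small GTPase that controls actin organisation, with control keratinocytes, either freshly isolated from epidermis or grown as primary cultures. Per the labels, the RhoA-null cells (written KO here) carried homozygous floxed RhoA alleles and a K5-driven Cre recombinase, which is active in basal keratinocytes, and the controls, called wildtype in the titles, carried a single floxed allele with the same Cre. The 10 samples formed 4 groups: 2 fresh control, 2 fresh KO, 3 cultured control and 3 cultured KO arrays. The titles call the samples biological replicates, without naming animals, so the p-values measure the spread between these samples.

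Per the labels' protocols, total RNA was amplified with an Affymetrix 3' IVT labelling kit and hybridised to Affymetrix whole-genome mouse expression arrays. The deposited table gives 1 linear intensity per probe set and array, made by the authors. The submitters' processing notes name MAS5, a program that turns probe brightness into probe set signals, and its version, scaling and background settings are not given in the sources used here. The intensities of fresh and cultured arrays appear to have been normalized separately, as their ranges differ. On the 6 cultured arrays the median intensity was 7.75 to 8, the highest value 111660 to 123446, and 53.9% to 54.3% of probe sets lay below 10. On the 4 fresh arrays the median was 64.1 to 64.8, the highest value 31542 to 32618, and 0.102% to 0.140% of probe sets lay below 10. Levels were therefore set against each other only within a condition, and cultured cells were compared with fresh cells by rank within each array. Many of the cultured values thus sit at a floor, and a fold against such a value depends on where the authors' procedure put that floor.

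Gene symbols came from the platform annotation, updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of 45037 probe sets, 34945 had 1 symbol, 932 had several and 9160 were unnamed here, and the named ones covered 18193 genes. Probe sets with several symbols or none were tested and counted but not named. For a gene with several probe sets, the one with the highest mean log2 intensity over all 10 arrays stood for the gene.

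Intensities were converted to log2 with no offset. Probe sets above the array's own median on at least 2 arrays of the condition were kept. The table used here held no array control probe sets, so no 3'/5' ratios of control transcripts were computed. KO and control arrays were compared by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, 2-sided), separately in cultured and fresh cells, with Benjamini-Hochberg adjustment at 0.05. The plan fixed before the data were examined was 1 fit over all 10 arrays. It was replaced because of this difference in scale and is reported as an alternative. The difference between the KO effects in culture and in fresh cells was tested per probe set from both limma fits, with their moderated standard errors combined.

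Gene lists for pathways and for cell types that a skin preparation could hold were fixed before the data were examined, with 1113 entries, of which 1025 matched a gene on the array. They were tested with limma's camera (preset inter-gene correlation 0.01) where at least 5 members were measured, and again with an estimated correlation. The results of 2 further lists are not reported here, and the adjusted p of the others were computed with those included. The difference between conditions in a list's mean was tested by exact permutation of the genotype labels within both conditions (120 assignments, smallest p 0.0167). Signals are given as mean ± SD over arrays and log2 changes with limma's standard error. For comparing cultured with fresh cells, probe sets in the top 10% of every array of one condition and in the lower 50% of every array of the other were counted, a rule set after the difference in scale was seen.

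The genes named were chosen by a rule fixed before the data were examined: Rhoa, the 10 largest rises and the 10 largest falls among genes past the threshold without overlap of the groups (or, where none passed, the 5 with the smallest p in each direction, said not to have passed), up to 4 members of each called list and, called or not, of the retinoid, SRF, basal, suprabasal and wound lists, and, among genes whose difference passed the threshold, the 10 largest differences between conditions in each direction. Members of lists called in both conditions are given as counts, with the names of those at an unadjusted p under 0.05 in both. Genes named outside this rule are marked as chosen after their values were seen.

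The number of arrays, 2 or 3 per group, limits the precision. On simulated data with 200 changed probe sets, the cultured procedure recovered 71% of 2-fold and 94% of 4-fold changes with 5 false calls, and the fresh procedure 35% and 74% with 4 false calls. With no change simulated, both made 0 calls. The simulated noise was independent between probe sets, and changes were placed only in probe sets above the median mean signal. These rates may therefore not hold for real arrays, which can shift as a whole, or for weak signals. The smallest p that an exact permutation test can give is 0.1 for 3 against 3 arrays and 0.333 for 2 against 2. Alternatives tried were quantile normalization, centring on the 75th percentile, an offset before log2, no filter and stricter filters, eBayes without a trend or robust, array weights, a replicate block, the mean over a gene's probe sets, stricter thresholds, the 10-array fit and leaving out each array in turn. The arrays hold no position information used here, so no coordinates are given.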

Results

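Expression was measured on 10 arrays: 2 control and 2 KO arrays of keratinocytes freshly isolated from mouse epidermis, and 3 control and 3 KO arrays of cultured primary keratinocytes. The design asks which transcripts differ between RhoA-null and control keratinocytes, whether these differences are alike in the tissue and in culture, and how cultured cells differ from fresh ones.

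Rhoa itself was read by 3 probe sets. In culture the probe set that stands for the gene, by its mean over all 10 arrays, did not pass the threshold, with 10123 ± 1027 signal units in control and 7892 ± 294 in KO (log2 change -0.35, SE 0.08, n = 3 per group, limma adjusted p = 0.156). The second gave 13200 ± 1961 against 10595 ± 343 (adjusted p = 0.272). In fresh cells the same probe sets read 3793 ± 377 in control and 4347 ± 72.2 in KO (adjusted p = 0.434), and 1627 ± 260 in control and 1910 ± 49.7 in KO (adjusted p = 0.494, n = 2 per group). The third read 5.27 in both cultured groups, at the floor, and 54.9 ± 22.1 against 49.7 ± 11.9 in fresh cells. Where these probe sets lie relative to the deleted part of the gene is not known here, so their levels neither check the genotype labels nor contradict them.

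Arrays of one group correlated at 0.990 to 0.996 in culture and at 0.976 to 0.991 in fresh cells, across probe sets, and no array repeated another. Arrays of different genotype correlated at 0.982 to 0.991 and at 0.967 to 0.989. The first principal component of the cultured arrays, with 46.0% of the variance, placed the 3 controls at -45.8 to -12.6 and the 3 KO arrays at 12.5 to 38.6. The second, with 25.2%, set both replicate 1 arrays apart, at 27.0 and 28.7. Among fresh arrays the first component, with 62.2%, set KO replicate 2 apart at 44.3. That array carried hair follicle transcripts far above the others: Krt25, a keratin of the inner root sheath, read 10946 there against 282 and 74.7 in the controls and 62.3 in KO replicate 1. Melanocyte transcripts were also highest on it (Tyrp1 718.6 against 38.3 to 95.9), and Cd74, carried by Langerhans cells, was lowest (1131 against 2654 to 4420). Krt25, Tyrp1 and Cd74 were chosen after their values were seen.

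In cultured KO keratinocytes Dsc1, a desmosomal cadherin of the suprabasal layers, rose from 224 ± 32.7 to 1292 ± 313 signal units (5.68-fold, adjusted p = 0.0358), and Ivl, which encodes the cornified envelope precursor involucrin, from 541 ± 146 to 2233 ± 325 (4.20-fold, adjusted p = 0.0444). The calprotectin genes S100a8 and S100a9, induced in activated epidermis, rose 3.57-fold and 4.53-fold (adjusted p = 0.0358 and 0.0386). Peg3, a paternally expressed zinc finger gene, fell from 470.1 ± 108 to 46.7 ± 18.6 (log2 change -3.38, SE 0.31, adjusted p = 0.0386), and Ocln, which encodes the tight junction protein occludin, from 877 ± 90.2 to 238 ± 63.6 (log2 change -1.91, SE 0.20, adjusted p = 0.0444). All these values have n = 3 per group.

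Among genes past the threshold the largest rise was that of Gsdmc2, a gasdermin gene, from 7.75 ± 2.23 to 101 ± 2.03 (log2 change 3.75, SE 0.20, adjusted p = 0.0159). Its control level lies at the floor of these arrays, so the size and rank of this rise depend on where that floor was set. Sh3kbp1, an endocytic adaptor gene, rose 7.96-fold (adjusted p = 0.0358) and Cotl1, an actin-binding protein gene, 5.70-fold (adjusted p = 0.0444). Teddm3 (6.13-fold), the cystatin family genes Stfa2l1 (6.03-fold) and Csta1 (4.51-fold), and Ctla2a (4.29-fold) completed the 10 largest rises. Ctla2a started near the floor, at 12.8 ± 1.23 in control. Among the falls were Tgfbr3, the TGF-beta coreceptor betaglycan (log2 change -1.97), Mab21l4 (-2.65), the G protein regulator Rgs2 (-1.67), Cyb5d2 (-1.47), the glutamate transporter gene Slc1a3 (-1.24), Efemp1 (-1.23), Stambpl1 (-1.09) and Popdc3 (-0.91), with adjusted p from 0.0159 to 0.0444. Mab21l4 reached the floor in KO cells, at 7.69 ± 1.92. Of the named genes with other probe sets, none had one called in the opposite direction. In fresh cells no probe set was called, so this says nothing there. An uncalled other probe set pointed the opposite way for Axl and Wwc1 in culture, both given below. The same held for Tpm2, Sulf2 and Nectin1 in fresh cells.

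**Figure D1:**
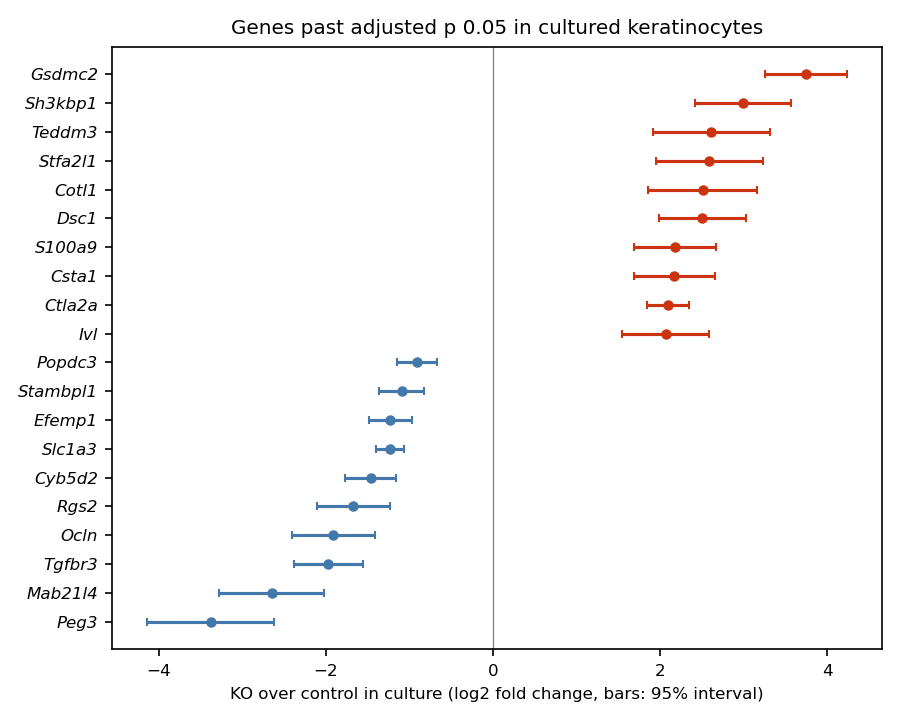
Log2 fold change, KO over control, of the 10 largest rises and 10 largest falls past the threshold in cultured keratinocytes (points, n = 3 arrays per group), with 95% intervals as bars. The points run from -3.38 for Peg3 to 3.75 for Gsdmc2, and the interval of each gene shown lies on one side of 0.

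Of 22682 probe sets tested in culture, limma called 62, with 41 higher and 21 lower in KO, for 33 genes (20 up, 13 down) by their representative probe set. At an unadjusted p under 0.05 there were 3548, where chance would give 1134, and 5069 (22.3%) showed no overlap between the groups, where chance gives 10%. The count rested on single arrays: it was 0 without control replicate 3, KO replicate 2 or KO replicate 3, 1 without control replicate 2, 26 without control replicate 1 and 95 without KO replicate 1. Other settings gave 0 (adjusted p under 0.01), 2 (no filter), 7 (no trend), 128 (75th percentile centring), 100 and 113 (stricter filters), 299 (array weights), 17 (a replicate block, with 7 of the 62 among them) and 395 (1 fit over all 10 arrays).

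Among the lists fixed beforehand, the suprabasal and cornified envelope list was higher in cultured KO cells, with 44 of its 48 measured members higher and 4 lower (mean log2 change 1.52, SE over arrays 0.50, median 1.04). The list test gave adjusted p = 4.71e-13, and adjusted p = 0.395 with an estimated correlation. Dsc1 and Ivl were called over all probe sets, and 22 members higher and 3 lower when adjusted over the list alone. Envelope precursor genes Evpl and Ppl and the transcription factor gene Ovol1 were at log2 changes of -0.61, -0.80 and -0.72, and are named after their values were seen. Rptn, which encodes the envelope protein repetin, read 8.73 ± 0.265 in control and 223 ± 139 in KO (adjusted p = 0.0643) and the desmoglein gene Dsg1b 327 ± 45.5 and 1004 ± 195 (adjusted p = 0.0528). Lce1b, Lce1c and Hrnr, at 11.7, 9.91 and 8.48 in control, lay near the floor like Rptn. Their folds, and so the list mean, depend on where that floor was set. The list's mean deviation was -1.20, -0.53 and -0.56 in controls 1 to 3 and -0.13, 1.14 and 1.28 in KO 1 to 3, so KO replicate 1 lay nearest to the controls.

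Cell cycle genes fell in cultured KO cells, with 53 of 57 S and G2/M genes lower and a mean log2 change of -0.32 (SE over arrays 0.08). The list test gave adjusted p = 3.94e-15, and adjusted p = 0.392 with an estimated correlation. No member was called by its representative probe set over all probe sets, 34 had an unadjusted p under 0.05, all of them lower, and 24 were called when adjusted over the list alone. The mitotic kinase gene Aurkb read 2591 ± 217 in control and 1605 ± 105 in KO (log2 change -0.69, adjusted p = 0.0669), and the replication genes Mcm3 and Pcna were at log2 changes of -0.44 and -0.21 and the cyclin gene Ccna2 at -0.52, short of the threshold.

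Wound and activation genes rose (35 measured, 27 higher, mean log2 change 0.75, adjusted p = 1.66e-05, and adjusted p = 0.352 with an estimated correlation). S100a8 and S100a9 were called over all probe sets and 5 members when adjusted over the list alone. The connexin gene Gjb6 (log2 change 2.16, adjusted p = 0.0562) and the matrix gene Tnc (1.45, adjusted p = 0.0643) came close. The p53 target list was higher, with 25 of 27 measured members higher and 2 lower (mean 0.60, adjusted p = 2.48e-08, and adjusted p = 0.392 with an estimated correlation), with 0 members called over all probe sets and 5 when adjusted over the list alone. Trp53inp1 (log2 change 1.28), the death receptor gene Tnfrsf10b (1.35), Bbc3 (1.12) and Mdm2 (0.55) had the smallest p among them, from 0.0918 to 0.153 after limma's adjustment over all probe sets.

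YAP and TEAD target genes fell in cultured KO cells (26 measured, 20 lower, mean log2 change -0.33, adjusted p = 5.45e-04, and adjusted p = 0.352 with an estimated correlation), with 3 called when adjusted over the list alone. Igfbp3 read 6969 ± 1303 in control and 1707 ± 699 in KO (log2 change -2.10, adjusted p = 0.0913), followed by Gadd45b (-0.86), the receptor kinase gene Axl (-0.73) and Wwc1 (-0.47). Cholesterol biosynthesis genes fell, with 19 of 20 lower (mean -0.38, adjusted p = 4.09e-07, and adjusted p = 0.480 with an estimated correlation) and 6 called when adjusted over the list alone. Their examples were Dhcr7 (-0.39), Insig1 (-0.60), Pmvk (-0.82) and Hmgcs1 (-0.34), none past the threshold singly. The cholesterol list's means overlapped between control and KO arrays (SE over arrays 0.15).

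Glycolysis and hypoxia genes fell as a list (25 of 32 lower, mean -0.31, adjusted p = 0.00451, and adjusted p = 0.635 with an estimated correlation). The call was lost without control replicate 2 (adjusted p = 0.104) and with array weights (adjusted p = 0.0514). The glucose transporter gene Slc2a3 read 106 ± 81.2 in control and 7.37 ± 0.355, at the floor, in KO (adjusted p = 0.0681), and Bnip3, Egln1 and Aldoc were at -1.36, -0.67 and -1.21 on the log2 scale. When adjusted over the list alone, 3 members were called. Epidermal barrier lipid genes went both ways, with 9 higher and 5 lower called when adjusted over the list alone. Their list call, upwards (mean 0.34, adjusted p = 0.0260, and adjusted p = 0.635 with an estimated correlation), was lost without KO replicate 2 (adjusted p = 0.145), with 75th percentile centring (0.0525) and with the mean over a gene's probe sets (0.0555). Plin2, a lipid droplet gene, had a log2 change of 0.98, Cyp4f39 1.33, Elovl4 0.89 and the desaturase gene Scd1 -0.89. The barrier lipid list's means overlapped between control and KO arrays (SE over arrays 0.15).

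Fibroblast and dermal genes, a marker list of another cell type, were higher in cultured KO cells (11 measured, 9 higher, mean log2 change 0.76, adjusted p = 0.00985, and adjusted p = 0.392 with an estimated correlation), with 3 higher and 1 lower called when adjusted over the list alone. The call was lost with no filter (mean 0.25, adjusted p = 0.289) and in the 10-array fit (mean 0.35, adjusted p = 0.0982). Fbln2 read 30.1 ± 1.16 in control and 167 ± 75.8 in KO, Vim 41.2 ± 21.6 and 106 ± 36.7, S100a4 626 ± 82.3 and 1111 ± 224, and Gsn 20487 ± 1113 and 15996 ± 1766, none past the threshold singly. In cultured control Col1a1, Col1a2, Col3a1 and Dcn read 6.98, 4.82, 5.52 and 3.98, at the floor, while Col5a1 and Pdgfra read 10.7 and 22.5. The call therefore does not show fibroblasts in these cultures. Other marker lists were not called: Langerhans cell and myeloid (adjusted p = 0.103), melanocyte (0.330), hair follicle (0.533), sebaceous gland (0.962, with mean -0.06 and a test pointing up) and blood, muscle, adipose and mast cell genes (0.523). T cell and endothelial genes had 4 measured members each and were not tested.

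SRF and MRTF targets, which respond to actin assembly, were not called in culture (adjusted p = 0.519). Egr2 was at a log2 change of -2.42, Cnn2 at -0.46 and Ccn1 at -1.03, none past the threshold. When adjusted over the list alone, 1 higher and 2 lower SRF targets were called.

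Neither retinoid list was called in culture. Retinoid metabolism and binding gave adjusted p = 0.817, with 3 members higher and 1 lower when adjusted over the list alone, and retinoic acid response genes gave 0.830, with 0. The retinoic acid binding protein genes Crabp2 and Fabp5 were 2.00-fold and 1.52-fold higher without passing (adjusted p = 0.175 and 0.178), and Sdr16c5 and Sdr16c6 were at log2 changes of -0.99 and 1.95. Meis2 was at 0.65, the retinoic acid-degrading enzyme gene Cyp26b1 at -0.63 and Krt19 at -0.71. Basal keratinocyte genes gave adjusted p = 0.0652, with Dlk2 at -0.87, Lamb3 at 0.32, Itgb4 at 0.48 and Lama3 at 0.37. That list passed without control replicate 1 (0.00202), without KO replicate 2 (0.0395), with no filter (0.0220) and with array weights (0.0361). Matrix and TGF-beta genes (0.0954) passed without control replicate 1 (0.00172) or KO replicate 3 (0.0401). Stress genes (0.606) passed without control replicate 1 (0.00172). Interferon (0.439), inflammatory (0.929, mean 0.07, median and test negative), junction (0.836), focal adhesion (0.698, median -0.02, mean 0.01) and NRF2 (0.606) lists were not called.

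In freshly isolated cells the cell cycle genes went the opposite way: all 55 measured members were higher in KO, with a mean log2 change of 0.54 (SE over arrays 0.14, 1.45-fold, n = 2 per group). The list test gave adjusted p = 4.25e-20, and adjusted p = 0.438 with an estimated correlation. No member was called over all probe sets, 37 had an unadjusted p under 0.05 and 35 were called when adjusted over the list alone. The centromere genes Cenpa and Cenpe read 497 ± 54.5 and 141 ± 20.9 in control and 861 ± 73.2 and 255 ± 17.3 in KO, and the mitotic kinase gene Plk1 167 ± 17.2 and 309 ± 31.8. The list's mean deviation was -0.15 and -0.39 in the controls and 0.20 and 0.33 in KO replicates 1 and 2, of which replicate 2 also carried the hair follicle transcripts.

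YAP and TEAD target genes fell in fresh KO cells as well (20 of 26 lower, mean log2 change -0.33, adjusted p = 1.46e-05, and adjusted p = 0.438 with an estimated correlation), with 2 higher and 12 lower called when adjusted over the list alone. Ccn1, a classical target, read 7652 ± 56.7 in control and 4792 ± 190.0 in KO, Igfbp3 3863 ± 1320.0 and 1203 ± 189, and Ptpn14 3125 ± 426 and 2026 ± 50.2, while Birc5, which the cell cycle list also holds, read 398 ± 85.6 and 782 ± 80.6. Wound and activation genes rose (21 of 27 higher, mean 0.54, adjusted p = 0.00903, and adjusted p = 0.438 with an estimated correlation), with 9 higher and 3 lower called when adjusted over the list alone. The call was lost without KO replicate 1 (adjusted p = 0.224), with the stricter filter within the condition (0.0857) and in the 10-array fit (0.0797). Stfa3, Sprr1b and Tnc had log2 changes of 3.54, 2.59 and 1.29, and the growth factor gene Ereg -1.31.

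Stress and immediate early genes fell in fresh KO cells (34 of 40 lower, mean -0.17, adjusted p = 2.44e-08, and adjusted p = 0.438 with an estimated correlation), with 14 called when adjusted over the list alone. Atf3 read 16020 ± 66.3 in control and 12733 ± 79.5 in KO, and Dnajb1, Ddit3 and Btg2 were at -0.45, -0.60 and -0.43 on the log2 scale. SRF and MRTF targets fell (29 of 38 lower, mean -0.09, adjusted p = 0.00131, and adjusted p = 0.438 with an estimated correlation), with 3 higher and 8 lower called when adjusted over the list alone, and lost the call without KO replicate 1 (mean -0.04, adjusted p = 0.0694) and in the 10-array fit (0.145), while the mean was -0.14 without KO replicate 2. Srf itself was at -0.52, while Fhl2 and Tpm2 were at 1.30 and 0.76. Retinoic acid response genes fell (19 of 25 lower, mean -0.23, adjusted p = 0.00167, and adjusted p = 0.438 with an estimated correlation), with 1 called when adjusted over the list alone. The mean was -0.15 without KO replicate 2 and -0.11 with no filter. Hoxa5, Cyp26b1, Ncoa7 and Hoxa2 were at -0.77, -0.63, -0.77 and -0.52.

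Langerhans cell and myeloid genes fell in fresh KO cells (25 of 29 lower, mean -0.49, adjusted p = 2.07e-05, and adjusted p = 0.721 with an estimated correlation), with 1 called when adjusted over the list alone, and the call was lost with the stricter filter over 10 arrays (0.0723). KO replicate 2 was lowest, with a mean deviation of -0.57 against 0.08 in KO replicate 1. The mean log2 change was -0.16 without KO replicate 2 and -0.82 without KO replicate 1. The macrophage gene Mpeg1 read 99.4 ± 5.08 in control and 39.8 ± 4.96 in KO, Adgre1 159.6 ± 16.1 and 81.8 ± 27.7, and Csf2ra and Ctss were at -0.65 and -1.16. Fibroblast and dermal genes rose (13 of 20 higher, mean 0.40, adjusted p = 0.0215, and adjusted p = 0.578 with an estimated correlation), with 1 called when adjusted over the list alone. Fbln1, Col5a2 and Col5a1 were at 0.55, 0.41 and 0.44, and the collagen gene Col3a1 read 22.2 in control, the 14.4th percentile of those arrays and thus near their background, and 88.2 in KO. That call was lost without control replicate 2 (adjusted p = 0.0742), without KO replicate 1 (0.293) and with both stricter filters (0.835, where the mean was 0.04, and 0.179).

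NRF2 targets rose in fresh KO cells (18 of 27 higher, mean 0.16, adjusted p = 0.0140, and adjusted p = 0.438 with an estimated correlation), with Aldh3a1 at 0.69, Gpx2 at 0.98, Akr1b8 at 0.60 and Taldo1 at 0.41. The p53 targets rose (20 of 27 higher, mean 0.21, adjusted p = 0.0191, and adjusted p = 0.725 with an estimated correlation), with Pmaip1 at 0.63, Ptprv at 1.03, Sulf2 at 1.34 and Btg2 at -0.43. Cholesterol genes fell (16 of 20 lower, mean -0.12, adjusted p = 0.0138, and adjusted p = 0.438 with an estimated correlation), with Msmo1 at -0.47, Fdft1 at -0.26, Hmgcs1 at -0.21 and Ebp at 0.35. Glycolysis and hypoxia genes fell (19 of 31 lower, mean -0.14, adjusted p = 0.0282, and adjusted p = 0.438 with an estimated correlation), with Bhlhe40 at -0.49, Ndrg1 at -1.22, Aldoc at -1.02 and Adm at -0.61. When adjusted over the list alone, 2 NRF2 members higher, 1 p53 target higher and 1 lower, 0 cholesterol genes and 5 glycolysis genes lower were called.

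Interferon response genes fell in fresh KO cells (24 of 28 lower, mean -0.18, adjusted p = 0.0138, and adjusted p = 0.750 with an estimated correlation), with Usp18 at -0.79, Isg20 at -0.74, Trim25 at -0.28 and Ifi27l2a at 0.71. Junction genes fell (24 of 37 lower, mean -0.07, adjusted p = 0.0140, and adjusted p = 0.591 with an estimated correlation), with Cgn at -0.99, Marveld2 at -0.53, Cldn1 at -0.35 and Nectin1 at 0.70. Matrix and TGF-beta genes fell (19 of 29 lower, mean -0.13, adjusted p = 0.0191, and adjusted p = 0.438 with an estimated correlation), with Timp3 at -1.22 and Fn1 at -1.23. When adjusted over the list alone, 0 interferon genes, 1 higher and 6 lower junction genes, and 3 higher and 6 lower matrix genes were called. The per-array means of the interferon and junction lists overlapped between genotypes (SE over arrays 0.20 and 0.07), so the arrays were not separated by them.

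Several of these list calls depended on 1 array or on the fit. Without control replicate 1 the calls of the interferon (0.183), matrix (0.126), NRF2 (0.0545) and glycolysis (0.143) lists were lost. Without control replicate 2 those of the p53 (0.235) and junction (0.0570) lists were lost, and without KO replicate 1 those of the p53 (0.0694), NRF2 (0.0694), junction (0.0884) and glycolysis (0.0974) lists. Without KO replicate 2 the interferon mean was 0.01 and the junction mean -0.14, and without KO replicate 1 the interferon mean was -0.37 and the matrix mean -0.27. The p53 mean was 0.33 and 0.09, and the junction mean -0.11 and -0.02, without control replicates 1 and 2. The 10-array fit ended the p53 (0.144), junction (0.0784), matrix (0.219), cholesterol (0.0784), NRF2 (0.273) and glycolysis (0.219) calls, and the stricter filter over 10 arrays the p53 call (0.0603).

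No fresh probe set passed the threshold. Of 22893 tested, limma called 0, with a smallest adjusted p of 0.153, while 2953 had an unadjusted p under 0.05 (1376 higher, 1577 lower), where chance would give 1145. A share of 46.9% showed no overlap between genotypes, where chance gives 33.3%. The 5 smallest p among higher genes, none of them past the threshold, were those of Stfa3, a cystatin gene (438 ± 159 in control, 4942 ± 557 in KO), Col3a1, near background in control, the transglutaminase gene Tgm3 (163 ± 14.1 and 502 ± 18.6), the kallikrein gene Klk6 and Endou. Among lower genes they were those of Gpha2 (log2 -1.79), Timp3, the fibronectin gene Fn1, Ccn1 and the Wnt agonist gene Rspo3 (-1.31), all at adjusted p = 0.153. The count was 11 without KO replicate 2, 945 without KO replicate 1, 0 without either control, and 393 in the 10-array fit, whose shared spread the cultured floor enters.

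The suprabasal list was not called in fresh cells (adjusted p = 0.899, mean -0.04, with a test pointing up), with 9 members higher and 3 lower when adjusted over the list alone. Tgm3, Klk6, Klk8 and Serpinb12 were at 1.63, 1.36, 0.91 and 2.50 on the log2 scale. Basal genes gave adjusted p = 0.163, with Krt15 at -0.22, Dst at -0.31, Cd44 at 0.57 and Krt14 at 0.17, and passed without control replicate 2 (0.0182). Retinoid metabolism genes gave 0.648, with Ces1d at -0.90, Fabp5 at 0.38 and Adh1 at -0.40. When adjusted over the list alone, 0 basal genes and 1 lower retinoid metabolism gene were called. Inflammatory (0.615), barrier lipid (0.839), sebaceous (0.161), melanocyte (0.418), T cell (0.101) and endothelial (0.762) genes were not called either. Focal adhesion genes (0.101) passed without KO replicate 2 (0.0158), with no filter (0.0494) and with the stricter filter over 10 arrays (0.0424). Without control replicate 1 the T cell list passed (1.05e-04), without control replicate 2 the sebaceous list (0.0405) and without KO replicate 1 the inflammatory list (0.0302). Melanocyte genes passed with no filter (0.00620) and in the 10-array fit (0.0465). Hair follicle genes gave 0.551 with both KO arrays but were called up without KO replicate 1 (mean 2.78, adjusted p = 4.51e-14) and down without KO replicate 2 (mean -0.55, adjusted p = 1.32e-05), and down with the stricter filter over 10 arrays (mean -0.19, adjusted p = 0.0264). Blood, muscle, adipose and mast cell genes had 2 measured members and were not tested.

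**Figure D2:**
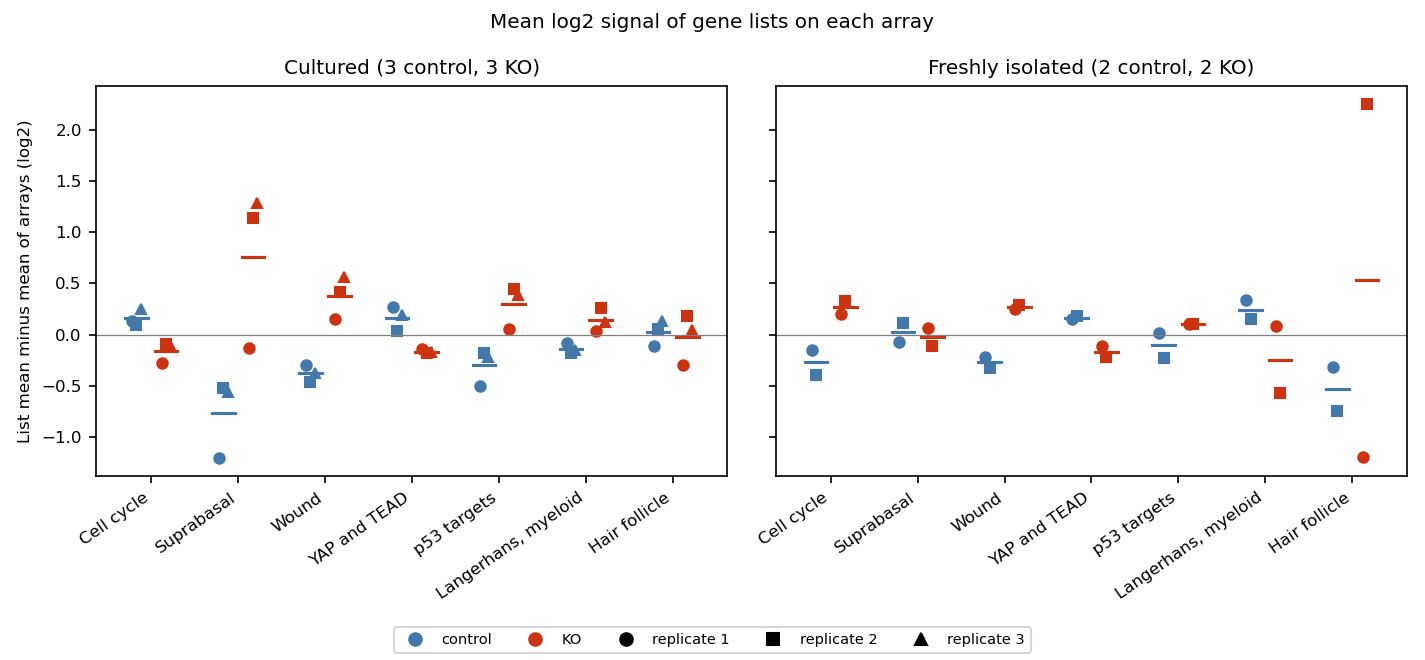
Mean log2 signal of 7 gene lists on each array, as the difference from the mean of the arrays of the same condition (points by replicate, bars at group means), for 3 + 3 cultured and 2 + 2 fresh arrays. Cell cycle genes lie lower in KO than in control in culture and higher in fresh cells, and the hair follicle list of fresh KO replicate 2 stands at 2.25.

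The KO effect differed between culture and fresh cells for 165 of 18773 probe sets tested (68 higher and 97 lower in culture), and 3350 had an unadjusted p under 0.05, where chance would give 939. Which direction held more calls depended on the setting. Higher and lower calls were 176 and 113 with a replicate block, 116 and 68 without cultured KO replicate 1, and 133 and 119 in 1 fit over all 10 arrays. With quantile normalization they were 78 and 130. Among genes past the threshold, the largest positive differences included Lor, the cornified envelope gene loricrin (log2 change 2.64 in culture, -1.06 in fresh cells, adjusted p of the difference 0.0234), Sh3kbp1 (2.99 and -0.35, adjusted p = 0.00508) and Dsc1 (2.51 and -0.10, adjusted p = 0.00957). The largest negative ones were those of Slc2a3 (-3.60 and 0.05, adjusted p = 0.0279), Peg3 (-3.38 and -0.20, adjusted p = 0.0166) and Mab21l4 (-2.65 and 0.22, adjusted p = 0.0116). The cultured KO signals of Slc2a3 and Mab21l4, 7.37 and 7.69, lie at the floor, so the size and rank of both depend on where that floor was set. Cell cycle members supplied 12 called genes, among them Aurkb (-0.69 and 1.01, adjusted p = 0.0468).

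As lists, cell cycle genes differed by -0.85 between the conditions (55 genes, exact permutation p = 0.0167, the smallest the design allows, adjusted p = 0.217 over 26 lists), with every KO array below every control in culture and above in fresh cells. Suprabasal genes differed by 1.54 (44 genes, exact permutation p = 0.0333, adjusted 0.289) and Langerhans cell and myeloid genes by 0.46 (10 genes, exact permutation p = 0.0167, adjusted 0.217), and none of these passed the correction. In cultured control the Langerhans cell markers Cd207, Cd74 and H2-Aa read 4.52, 3.41 and 3.93, at the floor, while Epcam and Cst3 of that list read 4437 and 4497. The difference of that list therefore cannot be read as one in Langerhans cells. YAP and TEAD targets differed by 0.002 (exact permutation p = 0.983), with means of -0.33 and -0.34. The sizes also depend on the authors' scaling, which appears to differ between the conditions. By the sex-linked transcripts given with the culture comparison, the fresh arrays read as female and the cultured ones as male. Sex and culture therefore cannot be told apart in these differences. The count of 165 rested on single arrays: it was 2 without cultured control replicate 3, 18 without cultured KO replicate 3, 71 without cultured KO replicate 2, 12 and 50 without fresh control replicates 2 and 1, 311 without cultured control replicate 1 and 1302 without fresh KO replicate 1, while other settings gave 5 (adjusted p under 0.01), 108 (no trend), 289 (75th percentile centring), 289 (a replicate block), 269 and 166 (stricter filters over 10 and the condition's arrays), 320 (array weights) and 252 (1 fit).

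**Figure D3:**
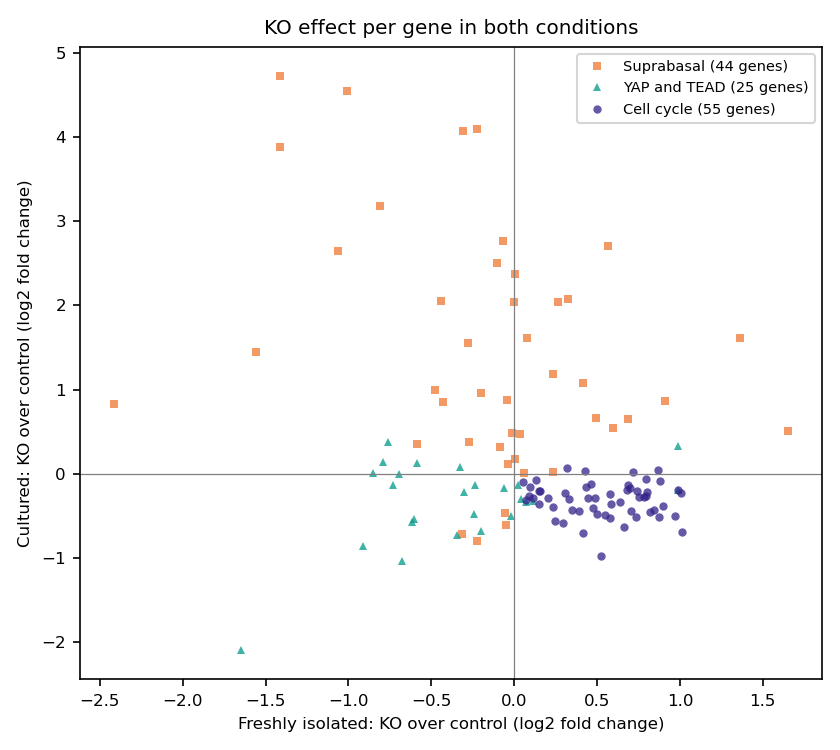
Log2 fold change, KO over control, of single genes in fresh cells (horizontal) and cultured cells (vertical), for suprabasal (44 genes), YAP and TEAD target (25) and cell cycle (55) genes measured in both. All 55 cell cycle genes lie right of 0 and most lie below 0, while suprabasal genes lie mostly above 0 and spread to both sides horizontally.

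Across 18773 probe sets the KO effects in the 2 conditions correlated weakly (Pearson 0.0674, Spearman 0.0219), and probe sets are not independent replicates. Of 52 probe sets called in culture and tested in both, 35 (67.3%) had the same sign in fresh cells, and of 1106 with an unadjusted p under 0.01 in culture, 51.4%. At that level 42 probe sets were lower in both, where independent lists would share 10.6, 16 higher in both (7.27), 29 lower in culture and higher in fresh cells (9.52) and 9 the reverse (8.11). The share among called probe sets was 100% without cultured control replicate 2, where 1 probe set was called.

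A list called in the same direction in both conditions holds many same-sign members even if its genes respond independently. The counts that follow therefore do not by themselves show agreement gene by gene. Among the lists called in both conditions, 15 of 25 YAP and TEAD targets had the same sign in both. Axl, Ccn1, Gadd45b, Igfbp3, Ptpn14 and Tead1 were lower at an unadjusted p under 0.05 in both, with Birc5 opposite. Another probe set of Axl pointed the other way in culture. In the wound list 20 of 26 had the same sign, and Gjb6, S100a8, S100a9, Sprr1b and Tnc were higher in both. In fresh cells S100a8 read 51.2 and 61.9 in control, 93.8 in KO replicate 1 and 379 in KO replicate 2, the array with the hair follicle transcripts. In the cell cycle list 21 members were lower in culture and higher in fresh cells at that level, and 4 of 55 had the same sign. The same sign was held by 21 of 26 p53, 15 of 20 cholesterol, 20 of 31 glycolysis and 4 of 7 fibroblast genes. Pmaip1 and Sulf2 (p53 list) were higher in both with Btg2 opposite. Another probe set of Sulf2 pointed the other way in fresh cells. Hmgcs1, Msmo1 and Pmvk (cholesterol list) were lower in both. Aldoc and Bnip3 (glycolysis list) were lower in both with Pgam1 opposite, and 0 fibroblast genes met that level in both.

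Cultured and fresh cells were compared by rank within arrays. In control cells 85 probe sets (51 genes) were in the top 10% of each fresh array and the lower 50% of each cultured one, and 40 (18 genes) the other way. In KO cells the counts were 79 and 41, and 62 and 32 probe sets met the rule in both genotypes. High in fresh cells were the MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1, the basal keratin gene Krt15, the immediate early genes Fosb and Nr4a3, the suprabasal genes Krt77, Calml3 and Serpinb7, and the histidine-degrading enzyme gene Hal. High in cultured cells were the chemokine gene Cxcl3, Il24, Sprr2h, Hmga2, Anxa3 and Procr. These genes were named after their ranks were seen. Of the lists, 4 of 36 Langerhans cell and myeloid, 3 of 56 suprabasal, 3 of 40 stress and 1 of 27 basal genes met the rule as high in fresh cells. So did 2 of 40 hair follicle, 1 of 16 sebaceous, 1 of 36 retinoid metabolism, 1 of 38 retinoic acid response, 1 of 46 SRF and 1 of 42 interferon genes. High in cultured cells were 2 of 37 wound and 1 of 46 inflammatory genes. Over all 45037 probe sets, 85 and 40 met the rule in control cells. No test backs these counts.

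The median member of the cell cycle list stood at the 73.6th percentile of a fresh control array and the 91.6th of a cultured one, the wound list at 59.3 and 85.3, the suprabasal list at 93.7 and 72.7, stress genes at 98.9 and 87.6, Langerhans and myeloid genes at 61.9 and 39.1 and T cell genes at 67.2 and 24.9. Widely expressed control genes stood at 97.6 and 98.8. Sex-linked transcripts separated the conditions too: Xist, made from the inactive X chromosome, read 8446 to 10416 on the fresh arrays and 3.77 to 3.82 on the cultured ones, while the Y-linked Eif2s3y read 11.8 to 13.4 and 4358 to 5385, and Kdm5d and Uty followed Eif2s3y. Within a condition the genotypes did not differ in this pattern. The fresh arrays thus read as female and the cultured ones as male. Every comparison between the conditions therefore also sets female against male samples, and sex and culture cannot be told apart.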

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

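The tests of hair matrix cells, basal cell share, chance between animals, culture-to-culture differentiation and the shared spread were chosen after the results were seen; the split count and the test without the late cornified envelope genes were chosen before.

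The KO effect differed between cultured and fresh cells for 165 probe sets, by a test of the difference itself that combined the standard errors of both limma fits. As differences of log2 changes, cultured minus fresh, the named genes past the threshold with the largest positive values were Lor (3.70), Sh3kbp1 (3.34), Teddm3 (2.77), Dsc1 (2.61), Cotl1 (2.25), Csta1 (2.18), Ctla2a (1.97), Kcnk2 (1.92), Abtb2 (1.81) and Trpm3 (1.78). Those with the largest negative values were Slc2a3 (-3.64), Peg3 (-3.17), Mab21l4 (-2.87), Ramp3 (-2.01), Aurkb (-1.70), Tgfbr3 (-1.62), Cenpm (-1.59), Pclaf (-1.54), Ocln (-1.52) and Cyb5d2 (-1.50), with adjusted p from 0.00508 to 0.0468 over these 20 genes. The values and ranks of Slc2a3 and Mab21l4 depend on the floor of the cultured arrays, where their KO signals lie (7.37 and 7.69). Ctla2a and Kcnk2 had cultured control signals near that floor (12.8 and 16.4), so the size and steadiness of their differences depend on it too. Trpm3 differs through fresh cells (-1.82 there, -0.05 in culture). It passed the filter in only 17 alternatives, against 21 for Lor, so the size of its difference may depend on weak signals. For the Langerhans cell and myeloid list given last here, the markers Cd207 and Cd74 lay at the floor of the cultured control arrays (4.52 and 3.41). Of the 20 genes, 18 lost the call without cultured control replicate 3, 16 without cultured KO replicate 3, 11 without fresh control replicate 2, 5 each without fresh control replicate 1 and cultured KO replicate 2, 4 without cultured control replicate 2 and 2 each without cultured KO replicate 1 and fresh KO replicate 2; Sh3kbp1 and Ctla2a kept it without each array and in their other alternatives. The list of Langerhans cell and myeloid genes differed by 0.46 (10 genes, exact permutation p = 0.0167, adjusted p = 0.217), and by 0.02 with the stricter filter within the condition (exact permutation p = 0.933); without fresh control replicate 1 or 2 the exact permutation p was 0.15, and without fresh KO replicate 2 (difference 0.27) or cultured KO replicate 2 (difference 0.41) it was 0.05.

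For the cultured comparison, the real split of the 6 arrays gave 62 calls and the highest of the other 9 of 10 splits gave 1. With 1 of 10 splits as large as the real one, the splits are too few for a share under 0.05.

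Cell cycle genes differed between the conditions by -0.85 on the log2 scale, lower in cultured KO and higher in fresh KO cells. Hair matrix cells, which divide fast, could raise them in fresh KO preparations. KO replicate 1 had a hair follicle list 0.66 below the controls (-0.663 over 31 genes). Its cell cycle shift was still 0.473, against a difference of 0.244 between the 2 controls, with 51 of 55 genes above both. The follicle keratins Krt25, Krt27 and Krt35 read 62.3, 34.9 and 36.1 there, below that array's median of 64.1. Of the matrix genes, Hoxc13 read 96.95 against 91.1 and 88.9 in the controls, and Msx2 96.6 against 106.6 and 108.5. These values show no clear rise of follicle transcripts on that array, but do not measure its share of matrix cells. For KO replicate 2, which carried hair transcripts, the explanation stays open, since its shift exceeded that of replicate 1 by 0.126, within the control difference. A larger share of basal cells stays open: the basal list's mean shift was -0.05, but its upper 95% bound from the error over arrays, 0.245, lies above 0.179, 1 part in 3 of the cell cycle shift. Chance differences between animals cannot be told apart from genotype in fresh cells, since the exact permutation p of 2 against 2 arrays is 0.333 at best. An effect of the RhoA deletion that differs between tissue and culture is a hypothesis that stays open beside these. So does sex, which was not tested: by sex-linked transcripts the fresh arrays read as female and the cultured ones as male. Sex and culture therefore cannot be told apart.

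Suprabasal genes differed by 1.54 (exact permutation p = 0.0333, adjusted p = 0.289), from their rise in cultured KO cells. Some members rose from control signals near the floor, so the size depends on where that floor was set. The late cornified envelope cluster, neighbouring genes with similar sequences, is argued against as the whole source, since the list's mean log2 change without its 12 members was 1.04 (36 genes, SE over genes 0.194), above 0.508, 1 part in 3 of the value with them. That error does not measure the spread between cultures, for which the whole list's SE over arrays was 0.50. Differentiation that varies from culture to culture may contribute and cannot be told apart from genotype, as the exact permutation p of 3 against 3 arrays was 0.1, the smallest possible, without overlap of the groups. The list difference was at exact permutation p = 0.1 without cultured control replicate 1, 0.0833 without cultured control replicate 2 or 3, and 0.05 without fresh control replicate 2 or fresh KO replicate 2. An effect of the RhoA deletion itself was not tested apart from this and stays open. The suprabasal difference between the conditions also cannot be told apart from their difference in sex.

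The 10-array fit called 393 fresh probe sets where the fit on fresh arrays called 0. The shared spread is a likely source: 66.7% of these calls lay in the lower 50% of the cultured arrays, against 16.4% of all probe sets tested, and the median residual SD of the called probe sets was 0.0197 on cultured and 0.133 on fresh arrays. A real effect of the deletion on part of these probe sets was not tested separately.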

How the results depend on the processing

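The stricter filter within the condition and the rank settings were added after the data were seen, and so was the use of the 10-array fit as an alternative. No setting changed the sign of the 21 named cultured genes. Each kept its call in 8 to 14 of 17 or 18 alternatives. Sizes moved too, as the log2 change of Slc1a3 ran from -1.26 to -0.60 over its alternatives. Cell cycle, suprabasal, p53, cholesterol, wound and YAP list calls in culture were kept in every alternative that used the preset inter-gene correlation. So were the cell cycle, YAP, stress and retinoic acid calls in fresh cells. With an estimated correlation, however, the list test called 0 of 27 lists in culture and 0 of 28 in fresh cells. Its smallest adjusted p were 0.352 and 0.438. All list calls, 9 in culture and 15 in fresh cells, therefore depend on the preset correlation. The array means of the cultured cholesterol list also overlapped between genotypes. The cell cycle difference stayed between -0.97 and -0.73 in its 16 alternatives. Its exact permutation p of 0.0167 is the smallest the design allows, so an unchanged p shows no stability beyond groups that do not overlap. Leaving out an array of a pair assumes the lone array varies like the other group. Whether the replicate numbers pair the samples is open: in culture, same-number correlations were 0.322, 0.0809 and 0.249, with numbers 1 and 3 but not 2 correlating best with their own. In fresh cells the single value 2 arrays per group can give was -0.0548; with a replicate block, cultured calls were 17, of which 7 were among the 62, fresh calls 0 and differences 289, and the basal list passed in culture (adjusted p = 0.0266). The lower 50% of the cultured arrays lies near the floor and limits which changes can be seen. The cause of the shifts below was not tested, except where fewer arrays, another threshold or another set of probe sets is the change itself.

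Cultured calls (62) were 0 at adjusted p under 0.01, 128 (73 up, 55 down) with 75th percentile centring, 2 with no filter, 100 and 113 with the top 40% over 10 or the condition's arrays, 7 without a trend, 299 with array weights, 395 (189 up, 206 down) in 1 fit, and 0 to 95 without single arrays. Fresh calls (0) were 393 in 1 fit and 0 to 945 without single arrays. Differences (165) were 5 at 0.01, 289 with centring, 269 and 166 with the top 40% over 10 or the condition's arrays, 108 without a trend, 320 with weights, 252 in 1 fit, and 2 to 1302 without single arrays. Same-sign share (67.3%) was 51.4% at an unadjusted p under 0.01, 100% with no filter (2 probe sets) and 55.9% to 100% without single arrays, with no value where 0 were called. The culture counts (125 control, 120 KO) were 383 and 340 with the top 20%, and 23615 and 23535 in 1 fit, which compares levels on scales that appear to differ.

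Means that changed sign, nearly all of lists not called: in fresh cells, endothelial 0.0768 with no filter and 0.0213 in 1 fit; with the filter over 10 arrays, hair follicle -0.192; with the filter within the condition, barrier lipid -0.0137. In culture, retinoic acid response 0.0188 with the filter within the condition and sebaceous 0.0078 with weights. The YAP difference was -0.00702 with no filter, -0.0336 and -0.00905 with the stricter filters. Without single arrays the fresh means ran from -0.113 to 0.0187 (basal), -0.133 to 0.0501 (suprabasal) and -0.373 to 0.00947 (interferon, called, lost without KO replicate 2). Further fresh means ran from -0.206 to 0.155 (inflammatory), -0.054 to 0.0407 (barrier lipid), -0.548 to 2.78 (hair follicle), -0.0478 to 0.348 (T cell) and -0.11 to 0.0277 (endothelial). The cultured means ran from -0.185 to 0.0509 (SRF), -0.102 to 0.196 (inflammatory), -0.0435 to 0.068 (focal adhesion), -0.0247 to 0.244 (NRF2), -0.0573 to 0.241 (stress), -0.147 to 0.0917 (hair follicle) and -0.182 to 0.0776 (sebaceous), and the YAP difference from -0.0639 to 0.0575.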

Other observations

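No test in this part was run beyond those reported above, and the genes below were chosen after their values were seen.

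In cultured KO cells Enah, an actin filament elongation factor gene, rose 1.82-fold (adjusted p = 0.0386), and a second probe set 1.91-fold. Inka2 rose 2.41-fold (adjusted p = 0.0358) and Wnt5a, a secreted Wnt ligand gene, 2.19-fold (adjusted p = 0.0444), from 33.5 ± 4.16 to 73.2 ± 3.91. Adam9, a membrane metalloprotease gene, fell from 8428 ± 1023 to 4490 ± 126 (log2 change -0.90, adjusted p = 0.0444). All have n = 3 per group.

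Fresh KO replicate 2 stood apart beyond the inner root sheath. Of 31 hair follicle genes measured, 20 were at least 1 log2 unit above each other fresh array, with a median difference of 3.15. Against the mean of the other 3 fresh arrays, Krt35 read 104-fold, Krt27 57.7-fold, Krt33a 49.4-fold and Tchh, the inner root sheath protein trichohyalin, 29.3-fold higher, while Hoxc13 and Msx2, transcription factors of the hair matrix, read 5.37-fold and 5.49-fold higher. Those other arrays read 36.1 to 84.4 for Krt35 and 34.9 to 138 for Krt27, partly below the array median, so the exact folds depend on the background. Gjb2 read 2211 on it and 122 to 225 on the others, S100a8 was 5.50-fold higher, Dct 5.79-fold and Mlana 10.5-fold, and Cd207, the Langerhans cell lectin, was at 0.411 of their mean.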
